A study of Mus musculus with 77 samples.

How the data were processed

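Single blastomeres were isolated by micromanipulation from mouse SCNT embryos cultured in vitro, their DNA was amplified over the whole genome and sequenced, per the labels' protocols. The deposited files hold 1 binary replication profile per cell for 77 cells and a table of cell annotations. The profiles give 1, -1 or 0 for each bin of 80 kb on chromosomes 1 to 19 and X. The genome build is mm9, per the submitters' processing notes. The aligner, the copy-number method and the tools are not given in the sources used here. The value 1 was read as replicated, -1 as not replicated and 0 as no call, because the share of 1 among called autosomal bins equals the replication score, in percent, that the authors give for each cell, to within 4.98e-09. The authors' annotation also gives a noise score per cell (the median absolute deviation, MAD, score), the embryo, the batch, a quality flag that all 77 cells pass, a manual filter that took out 0 of them, and a 2-somy setting of the authors' hidden Markov model for all 77. The deposited binary states are of no unit, the replication score is a percent, and the noise score is a score, per the file headers. Reads and depth per cell are not part of these files, so no counting interval is given, and the number of called bins stands in for coverage. Of 32973 bins, 1077 were called in no cell and 13420 autosomal bins were called in every cell. Profile columns that matched no sample numbered 0.

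A statement on a stage difference rests on embryos, since cells of one embryo are not independent. Cell values were averaged per embryo and differences in means were tested by two-sided permutation of embryo labels, exact with fewer than 10 embryos in a group and otherwise with 100000 resamples. The tests measure the spread between embryos, and the batch is confounded with the stage in part, as the earlier batch holds no 8-cell cell. Mid-S cells had 30 to 70% of called autosomal bins replicated. Agreement was the mean phi coefficient over pairs of mid-S cells of different embryos, over autosomal bins called in both. Sharpness, shares of early and late bins, and changes of state used equal numbers of cells per stage drawn within strata of 5 points of replicated percent, with 1000 draws for the value and 5 draws for each other split of the embryos. Runs and changes of state were taken along called bins. Chromosome and chromosome-end values are the replicated percent minus the autosomal replicated percent of the same cell, and their distance from 0 was tested by an exact sign-flip test over embryos. Chromosome ends are the outermost 10 Mb with called bins. Sharpness expected without a shared order came from 20 sets of profiles, each shifted along the genome by a random distance.

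Windows of 1 Mb with at least 6 called bins in at least 8 cells per stage were averaged per embryo and tested with limma 3.58.1 in R 4.3.3 with stage and the embryo's mean autosomal replicated percent as terms and Benjamini-Hochberg adjustment. The rule for named regions was the 10 with the largest change in each direction among those with adjusted p under 0.05 and the same direction in both title sets that hold both stages (from cell values minus the cell's autosomal replicated percent, without a fit), and the 5 earliest and 5 latest regions over both stages, with adjacent windows merged. The rule for chromosomes was X and the 3 highest and 3 lowest autosomes per stage. The comparisons, the tests between the stages, this rule and most alternatives were fixed before the data were examined. The sign-flip tests against 0, the tests between batches within the 4-cell stage, the shifted profiles and the tests on blocks and on cells of one embryo were added after they had been seen. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9.

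The window test was tested on simulated data with the design of the comparison, 2537 windows and 200 changed ones. It recovered 22% of windows changed by 20 points and 82% of those changed by 40 points, and 7 of its 111 calls were unchanged windows. The simulated values had normal noise, independent between windows, equally wide at both stages and without the bounds of a percent. They held no batches and no long blocks. How the window test behaves with these features of the real windows was not tested. The agreement test was tested on simulated cells over 30890 autosomal bins. It passed the threshold in 0 of 20 simulations without a difference and in 20 of 20 with a mean difference of 0.215, which is larger than the one measured, so its power at smaller differences was not tested. The simulated embryos of this test held equal numbers of cells, with no likeness within an embryo, no batches and no long blocks. How the test behaves with these features of the real cells was not tested. The search for blocks found all 20 planted blocks of 60 Mb and 1 other.

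Long single-state blocks were not among the planned measurements. Runs of up to 3 bins inside a longer run were filled before blocks of 40 Mb or more were listed. Alternatives chosen beforehand were mid-S ranges of 40 to 70% and 20 to 80%, each title set that holds both stages alone, the later batch alone, bins called in every cell, Cohen's kappa, pairs of cells within 10 points of each other, other window sizes and size thresholds, other end lengths, thresholds of 90 and 10% for early and late bins, dropping runs of 1 bin, and inclusion of X. Alternatives added after the data were seen were leaving out cells with blocks or the bins of the blocks, blocks of 30 and 50 Mb, blocks in mid-S cells alone, embryos with 2 or more cells, bins called in at least 80% of cells, and leaving out 1 embryo at a time. Replication timing of gene lists was foreseen but not computed, since no gene annotation of build mm9 was used here, and the regions are given by position alone.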

Results

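The data are single-cell replication profiles of mouse embryos made by somatic cell nuclear transfer (SCNT), in which the nucleus of a somatic cell takes the place of the oocyte's own. Each sample is 1 blastomere of an embryo of the BDF1 strain, and single-cell Repli-seq reads from its DNA copy number which parts of the genome it had already replicated. The labels define a 4-cell and an 8-cell group, with 28 cells of 14 embryos and 49 cells of 12 embryos. The embryo was taken as the replicate in the tests between the stages, since the authors' cell annotation names the embryo of every cell. An embryo contributed 1 to 4 cells at the 4-cell stage and 1 to 8 cells at the 8-cell stage. The files give, for each of 32973 bins of 80 kb in genome build mm9, whether the bin was replicated, not replicated or not called. Between 27057 and 29849 of the 30890 autosomal bins were called per cell at the 4-cell stage and between 27235 and 29848 at the 8-cell stage. Read depth is unknown, because the files hold calls and not reads. The annotation places the cells in 2 batches. The earlier batch holds 12 cells of 7 embryos, all at the 4-cell stage, and the later batch holds the other 16 cells of 7 embryos at that stage and all 8-cell cells. Values within the later batch are therefore given beside pooled ones where they differ most. No pooled p-value for a stage difference accounts for a difference between the 2 batches.

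The share of called autosomal bins that were replicated, which places a cell in S phase, ran from 12.6% to 93.7% at the 4-cell stage and from 12.9% to 94.8% at the 8-cell stage. The authors annotated all 77 cells as S phase. The embryo means were 61.7% ± 22.1 (SD, n = 14 embryos) and 54.4% ± 16.6 (SD, n = 12 embryos), and the difference of -7.29 percentage points was smaller than the spread between embryos (two-sided permutation test with 100000 resamples, p = 0.36). In the later batch alone the 4-cell embryos lay at 76.3% ± 14.5 (SD, n = 7), a difference of -21.8 points to the 8-cell embryos (two-sided exact permutation test, p = 0.0084). Without the cells that hold long single-state blocks, described below, the pooled difference was -1.45 points (two-sided exact permutation test, 9 against 12 embryos, p = 0.871). In cells with such blocks the replicated percent also reflects the blocks. In the later batch 13 of 16 4-cell cells held one, so the difference there does not show a later position in S phase. The cells of 4-cell embryos 4 and 5 had 15 to 18 autosomes at least 98% replicated. They changed state at most 3.25 times per 1000 called autosomal bins. Because cells lay at unlike positions in S phase, the comparisons of replication order, runs, chromosomes and windows used cells with 30 to 70% of bins replicated, called mid-S cells here. These were 18 cells of 9 embryos at the 4-cell stage, 10 of them from 5 embryos of the earlier batch, and 28 cells of 10 embryos at the 8-cell stage.

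**Figure D1:**
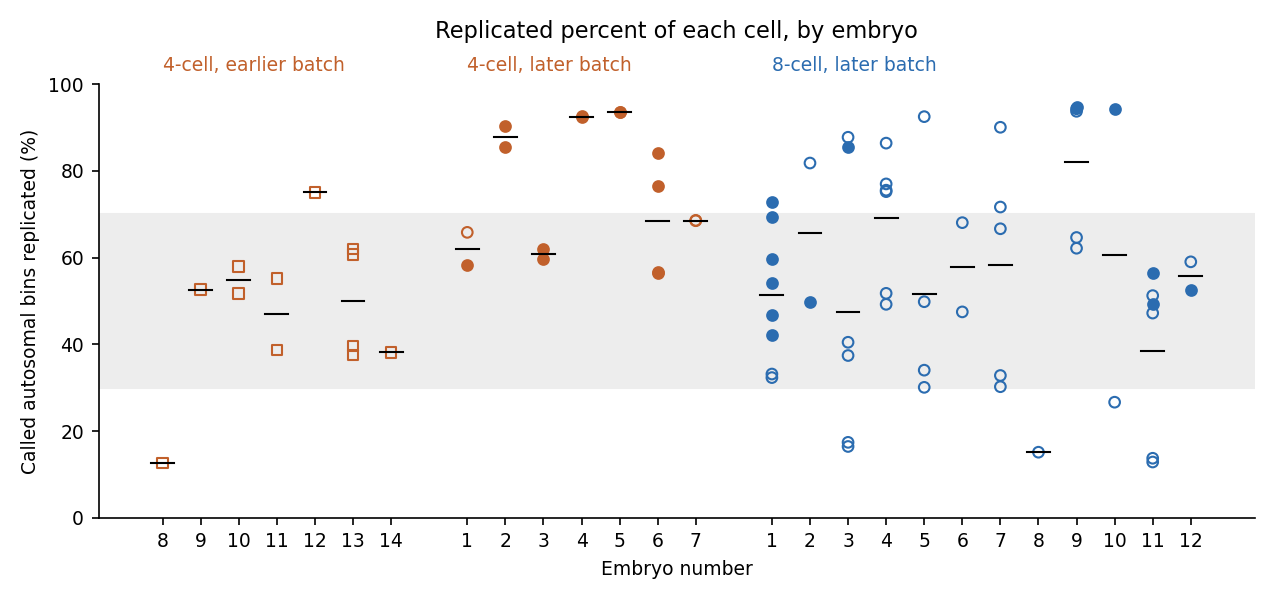
Replicated percent of called autosomal bins (vertical axis) in each of the 77 cells, by embryo number within stage and batch (horizontal axis). Squares are earlier-batch and circles later-batch cells, filled symbols are cells that hold a block of one state of 40 Mb or more, bars are embryo means, and the grey band marks 30 to 70%. The 4-cell embryos of the later batch averaged 76.3%.

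The first question was whether both stages replicate the genome in a common order. The regions named next were picked by their mean over both stages and so serve as examples only. Among 1-Mb windows, those at chromosome 15 from 85000001 to 86000000 and at chromosome 16 from 32000001 to 33000000 were replicated in 100% of the bins called in mid-S cells of both stages. The next earliest were at chromosome 5 from 124000001 to 125000000, chromosome 5 from 108000001 to 109000000 and chromosome 18 from 35000001 to 36000000, each with 100% at the 4-cell stage and at least 99.2% at the 8-cell stage. The latest region was at chromosome 7 from 77000001 to 79000000, with 0.926% ± 2.11 (SD, n = 9 embryos) replicated at the 4-cell stage and 0.119% ± 0.376 (SD, n = 10) at the 8-cell stage. The region at chromosome 14 from 117000001 to 118000000 had 1.28% and 0.11%, and that at chromosome 6 from 105000001 to 106000000 had 0.427% and 1.54%. The other late regions were at chromosome 7 from 101000001 to 103000000, with 1.18% and 1.86%, and at chromosome 4 from 91000001 to 92000000, with 2.14% and 1.15%. Of 2382 autosomal windows, 291 were at least 90% replicated at the 4-cell stage and 349 at the 8-cell stage, 189 of them at both. At most 10% replicated were 135 and 326 windows, 83 of them at both. The mid-S cells had a median replicated percent of 57.3% at the 4-cell and 49.5% at the 8-cell stage, and these counts were not matched for it. Across 29718 autosomal bins, which are not independent replicates, the share of mid-S cells with the bin replicated correlated between the stages with Pearson's r = 0.881 (bootstrap SD over embryos 0.0361) and Spearman's rho = 0.87. Random sets of 9 cells gave r = 0.851 between sets of the 4-cell stage, 0.918 between sets of the 8-cell stage and 0.821 between stages. These sets were drawn by cell and not by embryo. Sets of the same stage could thus share embryos, which sets of different stages cannot, and this may raise the values within a stage. In the later batch alone, with 8 4-cell cells, r between the stages was 0.746.

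The second question was whether cells of one stage follow that order equally closely. Mid-S 8-cell cells resembled each other more than mid-S 4-cell cells did, but the low values came from 4-cell embryos of the later batch. The mean phi coefficient of the binary states, over pairs of cells from different embryos, was 0.382 in 141 pairs of 4-cell cells and 0.548 in 340 pairs of 8-cell cells. This difference of 0.166 was larger than most other groupings of the embryos gave (two-sided exact permutation test, 9 against 10 embryos, p = 0.00816). It was 0.11 without 4-cell embryo 6 (exact permutation p = 0.0269) and 0.105 without the cells that hold long single-state blocks, described below (exact permutation p = 0.0479). Pairs of a 4-cell and an 8-cell cell had a mean phi of 0.431 (504 pairs). The mean of the within-stage values exceeded it by 0.0338 (two-sided exact permutation test, p = 3.2e-05), and by 0.0634 in the later batch alone (exact permutation p = 0.000999). Among 4-cell pairs, phi averaged 0.513 ± 0.0627 (SD over 37 pairs) within the earlier batch, 0.264 ± 0.116 (SD over 24 pairs) within the later batch and 0.357 ± 0.122 (SD over 80 pairs) between the batches. In the later batch alone the 8-cell value was higher by 0.284 (two-sided exact permutation test, 4 against 10 embryos, p = 0.012). The 4-cell embryos of the earlier batch differed from the 8-cell embryos by 0.0347, which was within the spread (two-sided exact permutation test, 5 against 10 embryos, p = 0.35).

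**Figure D2:**
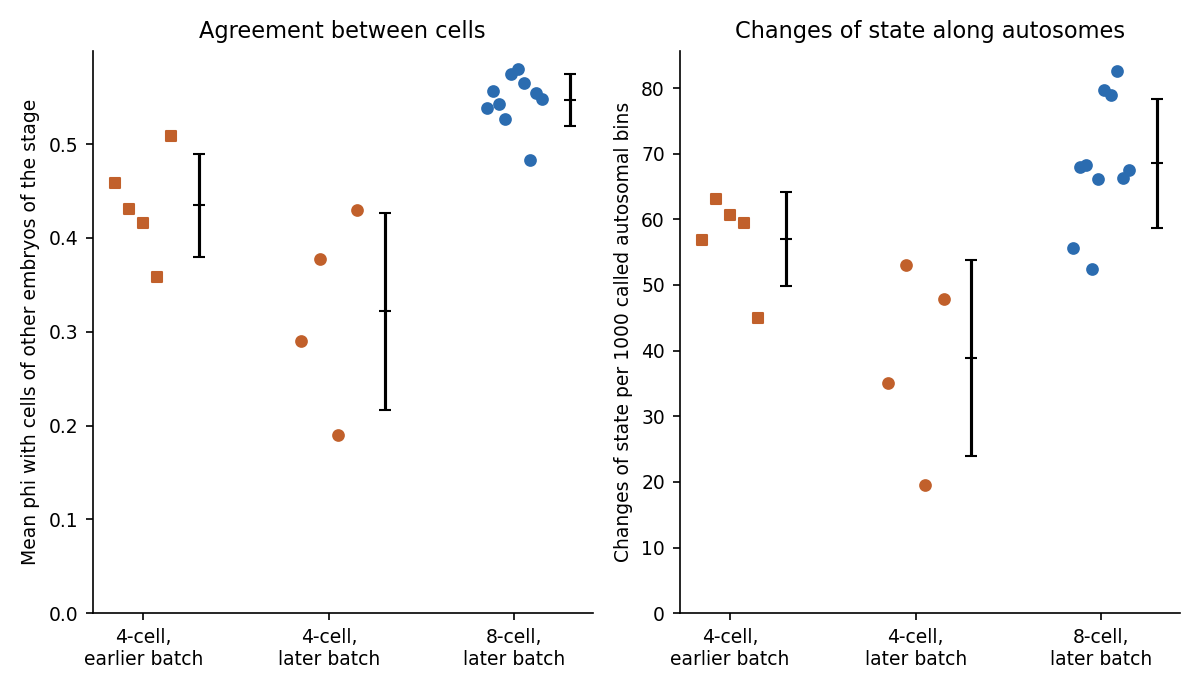
Left, mean phi of the mid-S cells of each embryo with cells of other embryos of the same stage (vertical axis, no unit). Right, changes between replicated and unreplicated state per 1000 called autosomal bins (vertical axis). Each point is an embryo, averaged over its mid-S cells without matching on S-phase position, and black bars are means with SD. The lowest 8-cell point of the left plot, at 0.483, lies above all 4 4-cell points of the later batch and 4 of the 5 of the earlier batch, whose values include pairs with later-batch cells; within the earlier batch phi averaged 0.513.

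Replicated and unreplicated stretches were shorter at the 8-cell stage. In sets of 11 cells per stage matched on replicated percent, 4-cell cells changed state 48.2 times per 1000 called autosomal bins and 8-cell cells 71 times. The difference was 22.8 changes (two-sided exact permutation test, 9 against 10 embryos, p = 0.00152). Cells could be drawn only from strata that held both stages. No cell of 8-cell embryos 2 and 5 was therefore drawn, and the value was the same without either. In the later batch alone no cell of 8-cell embryos 2, 3, 4 and 5 was drawn. Their labels still entered the permutations, so fewer embryos stand behind the values than the tests name. The same holds for run lengths and sharpness. The median replicated run was 1.18 Mb at the 4-cell and 0.834 Mb at the 8-cell stage (difference -0.349 Mb, two-sided exact permutation test, p = 0.00685), and the median unreplicated run was 0.819 Mb and 0.652 Mb (difference -0.167 Mb, two-sided exact permutation test, p = 0.0147). The unreplicated runs no longer passed without 8-cell embryo 6 (-0.123 Mb, exact permutation p = 0.0668) or without the cells that hold long single-state blocks, described below (-0.163 Mb, exact permutation p = 0.059). Within the later batch the runs differed by -0.572 Mb and -0.186 Mb (exact permutation p = 0.004 and 0.024) and the difference was 32.5 changes (two-sided exact permutation test, 4 against 10 embryos, p = 0.000999, the smallest that its splits can give). Against the 4-cell embryos of the earlier batch it was 11.9 changes and did not pass (two-sided exact permutation test, p = 0.0803), and within the 4-cell stage the later batch had 24.2 fewer changes, a difference of -24.2 (two-sided exact permutation test, 4 against 5 embryos, p = 0.0238).

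The sharpness of the average profile, taken as the SD across 20831 autosomal bins of the share of matched cells with the bin replicated, was 32.7 percentage points at the 4-cell and 36.1 at the 8-cell stage. The difference of 3.45 points was within the spread between embryos (two-sided exact permutation test, p = 0.0943). In the later batch alone it was 5.93 points and passed the threshold (two-sided exact permutation test, 4 against 10 embryos, p = 0.038). It also passed without 4-cell embryo 7 (4.8 points), 4-cell embryo 10 (4.15 points) or 8-cell embryo 6 (4.18 points), by the same exact test with p of 0.0195, 0.0469 and 0.0386. Without the cells that hold long single-state blocks it was 0.865 points (exact permutation p = 0.515). Both values lay above the 14.4 points obtained when the profiles of the drawn 8-cell cells were shifted along the genome at random. Bins replicated in at least 80% of the cells made up 41.7% of bins at the 4-cell and 47.6% at the 8-cell stage, and bins replicated in at most 20% of the cells made up 19.7% and 23.5%. Without the cells that hold long blocks these shares were 38.4% and 40.3% for early and 23.3% and 24.1% for late bins, and the summed stage difference was 2.67 points in place of 9.69, while in the later batch alone it was 16.9 points. The shifted profiles gave 12.6% and 0.414% with all mid-S cells, 7.61% and 1.09% without the cells that hold long blocks, and 23.7% and 0.848% in the later batch. These 3 sets rest on 11, 8 and 7 drawn cells per stage and on 20831, 28200 and 20923 bins, so their shares are not directly comparable.

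Chromosome 17 lay above the genome at both stages, and chromosomes 14 and X below it. Each chromosome's replicated percent was set against that of all autosomes of the same cell, so that a positive value means earlier replication than the genome. At the 4-cell stage chromosome 11 was highest, at 10 ± 10.2 percentage points (SD, n = 9 embryos), but did not pass the adjusted test. Chromosome 17 lay at 6.67 ± 4.05 points, positive in 8 of 9 embryos, and chromosome 9 at 6.43 ± 3.96 points, positive in all 9. Among the lowest were chromosome 3 at -8.61 ± 10.2 points, chromosome 14 at -8.4 ± 3.52 points and chromosome 10 at -6.23 ± 19.4 points, where embryo 6 alone lay at -56.4. Chromosome X lay at -11.5 ± 8.81 points, below 0 in all 9 embryos. In the 4 4-cell embryos of the later batch, too few to pass a sign-flip test, chromosome 11 lay at 3.48 and chromosome X at -7.3 points. Chromosomes 9, 14, 17 and X differed from 0 at this stage (two-sided exact sign-flip test, Benjamini-Hochberg over 20 chromosomes, adjusted p of 0.026 for 9, 14 and X and 0.0391 for 17). With the bins of long single-state blocks left out, which was decided after the data were seen, chromosome 9 lay at 3.33 points and no longer passed the adjusted test, and chromosome 11 lay at 4.27 points, below chromosomes 4, 5, 12, 17 and 19. Without the cells that hold such blocks, which left 7 embryos, none of chromosomes 9, 14, 17 and X passed (7.93, -6.51, 4.83 and -13.6 points, exact sign-flip test, adjusted p of 0.0781, 0.104, 0.0893 and 0.0893). At the 8-cell stage chromosome 11 lay at 11.3 ± 7.4 points (SD, n = 10 embryos), chromosome 17 at 7.58 ± 2.14 and chromosome 19 at 7.5 ± 4.95. The lowest autosomes were chromosome 14 at -9.76 ± 1.87 points, chromosome 3 at -6.67 ± 2.15 and chromosome 12 at -6.45 ± 15.1, where embryo 2 alone lay at -49.3, and chromosome X lay at -9.62 ± 9.79, below 0 in 8 of 10 embryos. The title sets that hold both stages differed for X, with -18.3 points in one and -3.83 in the other at the 8-cell stage and stage differences of -16.3 and 8.82 points. All 7 passed the same test (two-sided exact sign-flip test, adjusted p from 0.00781 to 0.0477), as did chromosomes 5 and 6. Chromosome 12 lay at -2.07 points with the block bins left out and at -1.71 points without the cells that hold blocks, and was then no longer among the 3 lowest autosomes. No chromosome differed between the stages after adjustment (two-sided exact permutation test, 0 of 20), and with all bins chromosome 7 alone had an unadjusted p under 0.05, with 6.29 points at the 4-cell and 0.00758 points at the 8-cell stage (p = 0.0231, adjusted p = 0.463, exact permutation test). This depends on the blocks: with their bins left out chromosome 7 had p = 0.163 in the same exact test, and chromosomes 2, 4, 6, 12 and 14 had an unadjusted p under 0.05. Without the cells that hold blocks it had p = 0.126, and chromosomes 2, 4, 8, 14 and 15 had an unadjusted p under 0.05, again exact and with 0 of 20 passing the adjustment. In the later batch alone chromosomes 5 and 7 had an unadjusted p under 0.05 (0.017 and 0.016, exact permutation test) and 0 of 20 passed.

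**Figure D3:**
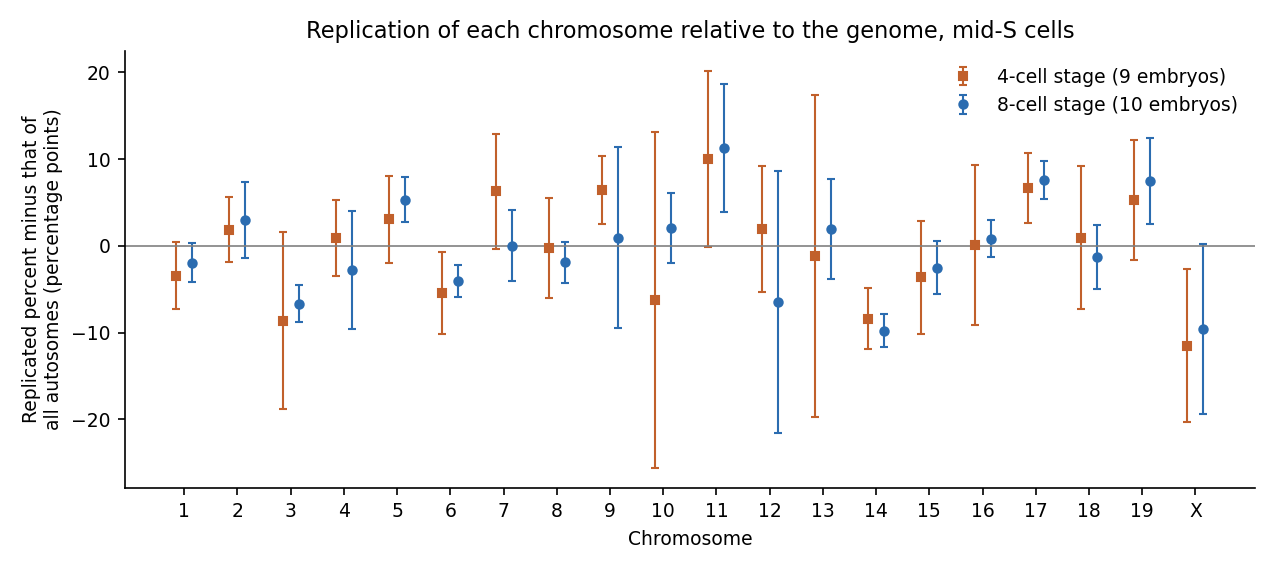
Replicated percent of each chromosome minus that of all autosomes of the same cell, in percentage points (vertical axis), by chromosome (horizontal axis), for mid-S cells. Points are means of 9 4-cell embryos (squares) and 10 8-cell embryos (circles), with SD; chromosome 14 lies at -8.4 points at the 4-cell stage and -9.76 at the 8-cell stage.

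The third question was where along the genome the stages differ. Of 2537 windows of 1 Mb, 18 differed (limma on embryo means with the embryo's autosomal replicated percent as covariate, Benjamini-Hochberg adjusted p under 0.05), 13 replicating later and 5 earlier at the 8-cell stage. Of these, 16 had the same direction in both title sets that hold both stages, 12 of them later and 4 earlier at the 8-cell stage. The largest delay was at chromosome 5 from 127000001 to 128000000, replicated to 82.2% ± 23.1 (SD, n = 8 embryos) at the 4-cell and to 17.1% ± 16.7 (SD, n = 10) at the 8-cell stage. Its fitted difference was -67.5 points (SE 9.35, limma adjusted p = 0.00204), and all 10 8-cell embryos lay below the 4-cell mean. Relative to each cell's autosomes and without a fit, the delay was -57.7 points in one of the title sets that hold both stages but -7.68 points in the other. A second window of that chromosome, from 134000001 to 135000000, went from 92.2% to 61% (fitted difference -31.6 points, limma adjusted p = 0.00549). On chromosome 4, the windows from 121000001 to 122000000, 127000001 to 128000000 and 152000001 to 153000000 were later at the 8-cell stage by fitted differences of -37.4, -40.3 and -43.7 points. For the last of these the fitted difference was 3.15 points, the other way, in one of the title sets that hold both stages. On chromosome 12, the windows from 12000001 to 13000000 and 69000001 to 70000000 had fitted differences of -39.6 and -24.7 points. The other windows named as later at the 8-cell stage were at chromosome 14 from 80000001 to 81000000 (-35.7 points), chromosome 6 from 123000001 to 124000000 (-32.9 points) and chromosome 2 from 4000001 to 5000000 (-25.6 points). In the opposite direction, chromosome X held 2 windows. The one from 125000001 to 126000000 went from 6.62% ± 13.9 (SD, n = 9) to 44.5% ± 37.3 (SD, n = 10), with a fitted difference of 47.4 points (limma adjusted p = 0.0462), and the one from 123000001 to 124000000 went from 16% to 47.4%. The window at chromosome 10 from 112000001 to 113000000 had 9.26% at the 4-cell and 40.4% at the 8-cell stage, and that at chromosome 6 from 58000001 to 59000000 had 28.9% and 48.6%. In one of the title sets that hold both stages, the chromosome 10 window had a fitted difference of -15 points, the other way. The chromosome 6 window differed by 18.8 points in one set and 2.44 in the other, relative to each cell's autosomes and without a fit. Without the cells that hold long single-state blocks, described below, 52 windows were called, 14 of them among the 18. Leaving out 1 embryo at a time gave 33 windows without 8-cell embryo 2 and 27 without 4-cell embryo 6. It gave 5 without 8-cell embryo 3, 11 or 12, 6 without 4-cell embryo 3 or 14 or 8-cell embryo 5, 7 without 4-cell embryo 10 or 8-cell embryo 7 or 9, and 8 without 4-cell embryo 1 or 9. It gave 9 without 4-cell embryo 11 or 8-cell embryo 6, and 10, 11, 12 and 15 without 8-cell embryo 1, 8-cell embryo 4, 4-cell embryo 13 and 4-cell embryo 7. No window was called earlier at the 8-cell stage in 13 of these 19 limma fits, and 1 was in the later batch alone, beside 17 later ones.

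**Figure D4:**
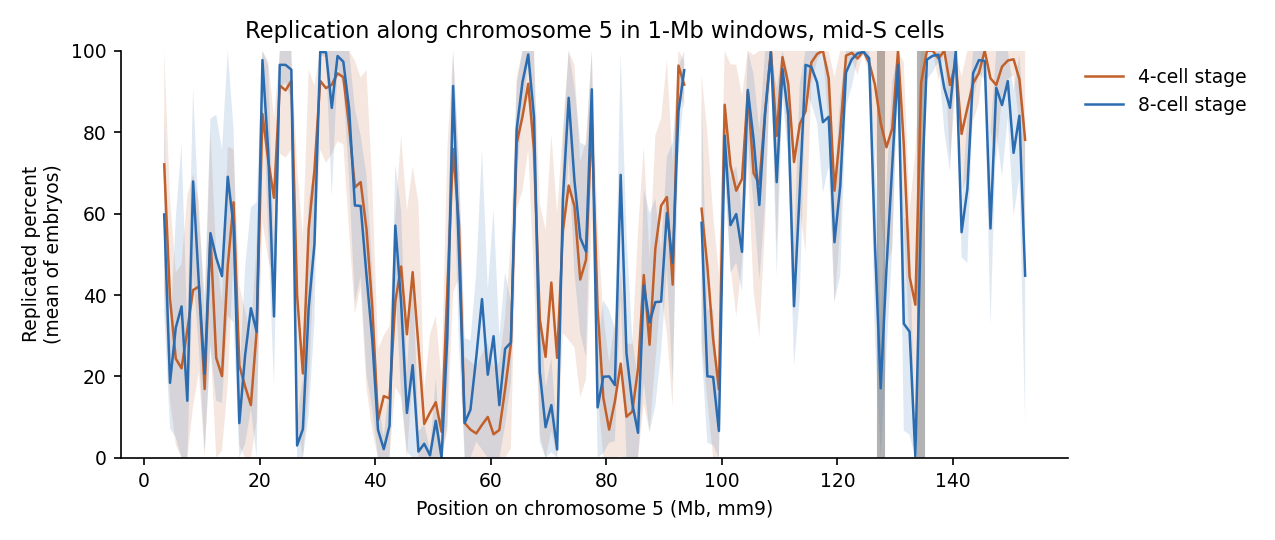
Replicated percent in 1-Mb windows (vertical axis) along chromosome 5 in Mb of build mm9 (horizontal axis), as the mean over embryos of mid-S cells at each stage, with shading for 1 SD. Grey bars mark the windows from 127 to 128 Mb and from 134 to 135 Mb, where the 8-cell line falls below the 4-cell line.

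Mouse chromosomes carry the centromere at one end, so each autosome has a centromere-proximal and a distal end. The distal 10 Mb were earlier than the genome at both stages, by 7.08 ± 3.13 percentage points (SD, n = 9 embryos) at the 4-cell stage and 6.69 ± 3.01 points (SD, n = 10) at the 8-cell stage (two-sided exact sign-flip test, p = 0.00391 and 0.00195). The proximal 10 Mb lay close to the genome at both, at 0.895 ± 4.22 and -0.226 ± 2.36 points. This depends on the length taken: the proximal 5 Mb were earlier than the genome, by 4.38 ± 3.78 and 3.14 ± 3.36 points (two-sided exact sign-flip test, p = 0.00391 and 0.0215). The distal minus proximal difference was 6.18 ± 6.42 points at the 4-cell and 6.91 ± 5.2 points at the 8-cell stage, and the stages did not differ past the threshold (two-sided exact permutation test, p = 0.786). With the later batch alone it was 2.41 ± 7.32 points at the 4-cell stage, and the stage difference was 4.51 points (two-sided exact permutation test, p = 0.217). In the later batch alone the proximal ends were lower by 4.25 points at the 8-cell stage, a difference of -4.25 (two-sided exact permutation test, p = 0.029).

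Some cells held whole chromosomes or long parts of them in one state. In cells near the middle of S phase this could also be the state of most of the cell. The 4-cell cells 12 and 14, for example, were 56.6% and 56.5% replicated and held replicated blocks. This was measured after the data were seen, as blocks of 40 Mb or more, unreplicated in a cell at least 40% replicated or replicated in a cell at most 60% replicated. Short runs of the other state were filled, and the length spans bins without a call. A block of 61.4 Mb on chromosome 14 of 4-cell cell 2, for example, held 405 called bins of 80 kb. There were 58 blocks in 26 of the 77 cells, with a median length of 78.1 Mb. Of these, 46 were unreplicated and 12 replicated, and 22 took in at least 98% of the called bins of their chromosome. Chromosome 9 held 8 blocks, and chromosomes 2, 7 and 19 held 6 each. At the 4-cell stage 13 of 16 cells of the later batch held a block and 0 of 12 of the earlier batch did. The embryo mean share of such cells was 78.6% ± 39.3 (SD, n = 7 embryos) in the later and 0% in the earlier batch (two-sided exact permutation test, p = 0.00466). At the 8-cell stage 13 of 49 cells held one, with an embryo mean of 24.6% ± 26.4 (SD, n = 12), lower by 54 points than in the 4-cell embryos of the later batch, a difference of -54 (two-sided exact permutation test, p = 0.00427). Which cells can hold a counted block depends on their replicated percent, which differs between these groups. Among mid-S cells 5 of 8 4-cell cells of the later batch and 9 of 28 8-cell cells held one, and the difference in embryo means of -35.4 points did not pass (two-sided exact permutation test, 4 against 10 embryos, p = 0.16). With both batches pooled, the difference between the stages of -14.7 points did not pass (two-sided permutation test, p = 0.355).

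The blocks recurred within embryos. Chromosome 2 was unreplicated in 99.9% and 100% of called bins in the 2 cells of 4-cell embryo 4, while 92.5% and 92.6% of their autosomal bins were replicated. In both cells 18 autosomes were at least 98% replicated, with 1.01 and 0 changes of state per 1000 called autosomal bins. Their profiles thus set chromosome 2 against the other autosomes and show almost no early and late parts within chromosomes. The profiles of these 2 cells differed in 417 bins, and no pair of the 77 cells was identical. Chromosome 2 also held a block in both cells of 4-cell embryo 2. In 4-cell embryo 5, cell 9 was unreplicated on chromosome 5 from 2960001 to 87280000 and cell 10 from 87280001 to 152480000, and both were unreplicated on the distal part of chromosome 9. Both cells of 4-cell embryo 3 held a block on chromosome 13. All 4 cells of 4-cell embryo 6 had chromosome 10 unreplicated. Its cell 12 had chromosomes 11, 12 and 19 unreplicated, while cell 14 had blocks of replicated state on each of them. Cell 14 had chromosomes 1, 4 and 8 unreplicated, and cell 12 had blocks of replicated state on each of those. In 8-cell embryo 1, chromosome 19 was unreplicated from about 17.8 Mb to its end in cells 1, 4 and 5, and replicated from 15760001 to 61280000 in cell 3. Over all pairs of cells of one embryo, 29 pairs of blocks overlapped by at least 50% of both lengths, 21 in the same and 8 in the opposite state.

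**Figure D5:**
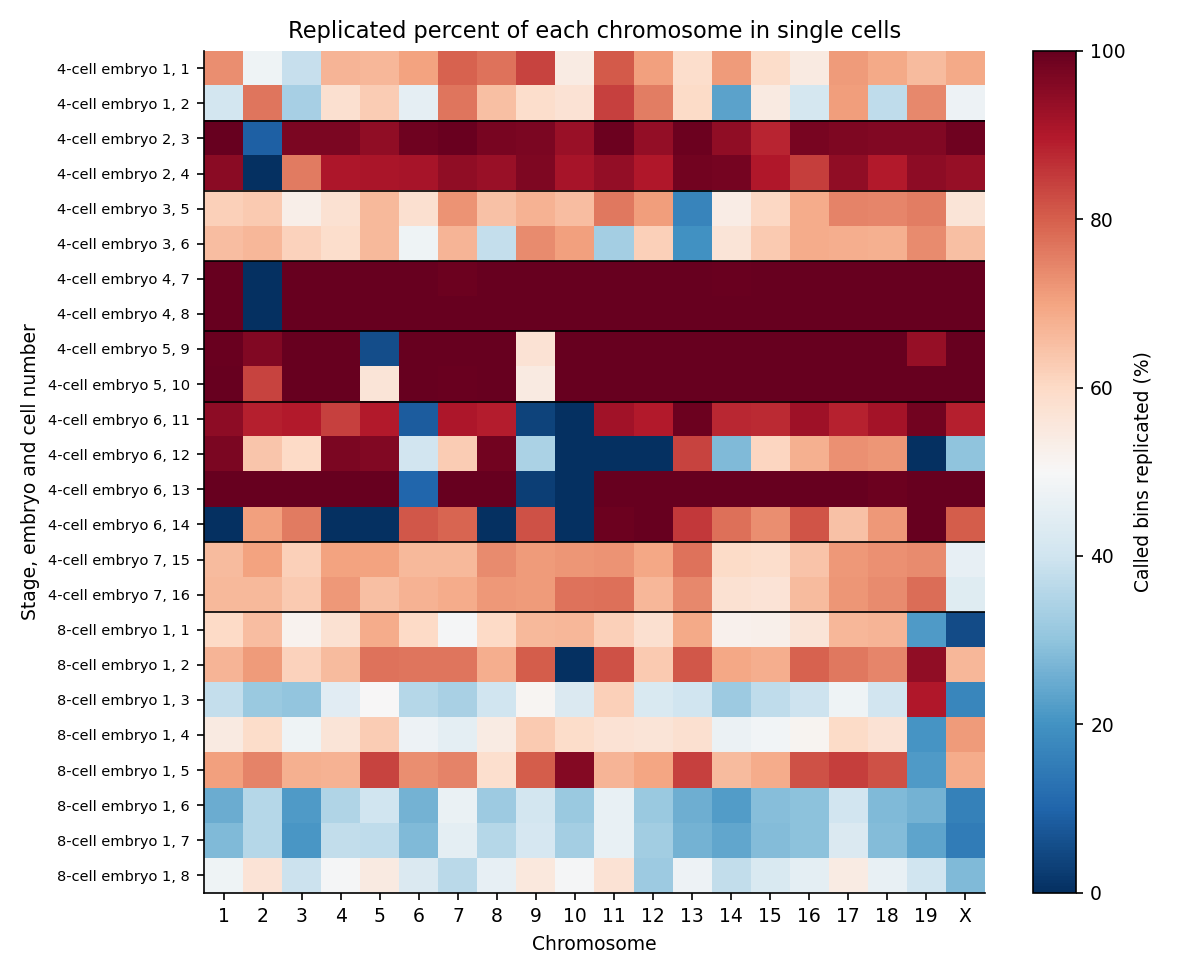
Percent of called bins replicated (colour, from 0 in blue to 100 in red) for each chromosome (horizontal axis) in each cell (vertical axis) of the 4-cell embryos of the later batch and of 8-cell embryo 1, with lines between embryos. Chromosome 10 is blue in all 4 cells of 4-cell embryo 6 and chromosome 2 in both cells of 4-cell embryo 4.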

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

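The test of each extreme embryo followed a fixed rule, and the tests of explanations for the blocks were chosen after the blocks had been seen. Over 52 groups of 9 or 10 embryos, 8 held a value that stood apart from the others of its group, where chance gives about 2.6. All 8 are values of single chromosomes relative to the genome in mid-S cells, and for 5 of them the embryo held a long single-state block on that chromosome. These 5 were 4-cell embryo 6 on chromosome 10 at -56.4 points (next -6.48), 4-cell embryo 3 on chromosome 13 at -42.5 points (next -6.84), 8-cell embryo 2 on chromosome 12 at -49.3 points (next -3.79), 8-cell embryo 12 on chromosome 9 at -27 points (next -1.09) and 8-cell embryo 1 on chromosome 10 at -7.87 points (next -0.7). The other 3 were 4-cell embryo 6 on chromosome 2 at 10.7 points (next 4.05), 8-cell embryo 2 on chromosome 4 at -21.4 points (next -4.99) and 8-cell embryo 2 on chromosome 7 at 10.3 points (next 1.26). For 8-cell embryo 2 only cell 9 was mid-S, so its values on chromosomes 4, 7 and 12 all come from that cell.

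Long blocks of one state lay on the same chromosomes as most of these values. Noise that arises in each cell apart from its embryo is argued against by the 29 pairs of overlapping blocks in cells of one embryo, since 10000 random deals of the cells to embryos within stage and batch gave at most 17 (p = 0.0001, the smallest they can give); without 4-cell embryo 6 there were 16, against at most 13 (p = 0.0001). Calls made at the edge of S phase were weighed as the whole cause, and 14 of the 26 cells with a block were 30 to 70% replicated. Blocks also move the replicated percent of a cell, so for cells such as 4-cell cells 12 and 14 this cannot decide. It argues against this cause for cells such as 8-cell cell 9, whose autosomes other than chromosome 12 were 28.4 to 64.7% replicated. Of the cells over 90% replicated, 5 of 5 at the 4-cell and 2 of 6 at the 8-cell stage held a block. A difference between the batches stays open, because within the 4-cell stage the embryo mean share of cells with a block was higher by 78.6 points in the later batch (62.5 points among mid-S cells, exact permutation p = 0.0476), and whether handling, embryo quality or donor differed between them is not given. A candidate explanation is loss and gain of chromosomes or chromosome parts at a division inside the embryo, which would leave opposite states in sister cells. In cells of one embryo lay 8 pairs of overlapping blocks of opposite state, against at most 7 in the random deals (p = 0.0001). They came from 2 embryos. Without 4-cell embryo 6 there were 3, against at most 4 in the random deals (p = 0.0077). All 3 share the same block, the replicated part of chromosome 19 in cell 3 of 8-cell embryo 1. Loss and gain thus remain a hypothesis.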

How the results depend on the processing

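The alternatives without blocks, with other block lengths, with blocks in mid-S cells, with embryos of 2 or more cells and without 1 embryo were chosen after the data were seen. The agreement difference kept its direction under all 10 alternatives (0.105 to 0.304) and passed in 8, and without each of 19 embryos (0.11 to 0.189). Changes of state kept their direction under 9 alternatives and passed in 7. The 2 title sets that hold both stages, called sets A and B here, are small. In set A, with 2 against 4 mid-S embryos, no exact permutation test can pass, so its p-values say nothing on stability. The agreement difference there was 0.304 and in set B 0.2999, within-stage minus between-stage agreement 0.0514 and 0.0582, and the difference in changes 14.6 and 42.7, none of which passed. For the changes in set A, all drawn 8-cell cells came from embryo 1. The profile correlation was 0.667 in set A, 0.663 in set B and 0.746 in the later batch. Limma called 0 windows in each set, with 161 and 539 at an unadjusted p under 0.05. The difference in replicated percent passed in set B (-28.4 points) and in the later batch (-21.8 points), and that in the share of cells with blocks in the later batch (-54 points) but not among its mid-S cells (-35.4 points) or among all mid-S cells (-0.635 points). Sharpness passed with cells of 20 to 80% (4.04 points) and in the later batch (5.93 points), and was 0.865 points without cells with blocks. Without 1 embryo it ranged from 1.97 to 4.8 points, the lowest without 4-cell embryo 6 and the highest without 4-cell embryo 7, and passed without 4-cell embryos 7 and 10 (4.15 points) and 8-cell embryo 6 (4.18 points). The windows numbered 11 with cells of 40 to 70%, 37 at 500 kb, 85 at 80-kb bins and 52 without cells with blocks, and from 5 (without 8-cell embryo 3, 11 or 12) to 33 (without 8-cell embryo 2) without 1 embryo.

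The sign turned in the following. The distal difference was 1.23 points in set A, 0.219 in set B and 0.26 in the later batch, and the distal minus proximal difference -0.0899 with ends of 20 Mb and -1.09 without cells with blocks. At the 4-cell stage, chromosome 11 lay at -0.198 points and chromosome 3 at 2.65 points in set B, and chromosome 10 at 0.31 points in set A. Of the named windows, which had passed, chromosome 4 from 152000001 had a fitted difference of 3.15 points in set B and chromosome 10 from 112000001 of -15 points in set A. The naming rule used differences without the limma covariate, which were -9.25 and 15.8 points there, so neither window meets it by the fitted values. The cause of these changes was not tested. Of 358 combinations of 14 named windows with alternatives, 174 kept direction and call and 182 kept direction without passing. Of 98 combinations of named chromosomes with alternatives, 60 kept both, 33 kept direction without passing and 3 turned direction. The remaining 2, for chromosomes 3 and 11 at the 4-cell stage, passed where the main value did not. Chromosome 9 at the 4-cell stage kept its call in 1 of 7 alternatives. What read depth limits is unknown. No paired analysis was possible because each embryo belongs to 1 stage. The alternatives for gene lists were not run, since the lists were not analysed here.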

Other observations

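Cells of one embryo were more alike than cells of different embryos, and both tests of this were chosen after the values had been seen, as were the other tests in this part except the comparisons of the stages themselves, pooled and in the later batch alone. The count of other splits was planned, but its threshold was written afterwards. Mid-S cells of one embryo had a mean phi of 0.587 over 50 pairs from 16 embryos, with the bins of long blocks left out, against 0.554 for random deals of the cells to embryos within stage and batch (10000 deals, two-sided permutation p = 0.02). Pairs from different embryos of a stage had 0.53. At the 8-cell stage the values were 0.611 in 38 pairs and 0.576 in random deals (permutation p = 0.0153), and at the 4-cell stage 0.513 in 12 pairs and 0.469 (permutation p = 0.178). Cells of one embryo also lay closer in replicated percent. Their replicated percent differed by 22.4 points on average over 123 pairs, against 26.3 points in random deals (permutation p = 0.0176), and by 11.7 points at the 4-cell stage (permutation p = 0.0433) and 24.5 points at the 8-cell stage (permutation p = 0.053). Whether the stages differ in this was not tested. Cells with long blocks were kept, and blocks shared within an embryo can also bring the replicated percents together. The cells of 4-cell embryo 4, for example, lay at 92.5 and 92.6% with chromosome 2 unreplicated in both. Nearness in S phase was not separated from shared blocks. A hypothesis is that blastomeres of one embryo keep a common timing and may replicate more alike for it. It was found and tested on the same data, cells closer in S phase also have more bins in common state, and cells of one embryo shared handling and amplification, which was not separated from the embryo.

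The lower agreement and fewer changes of state at the 4-cell stage were weighed against 5 technical explanations and the stage itself. The long blocks are argued against as the whole cause, because with their bins left out the agreement still differed by 0.143 (exact permutation p = 0.00695). The earlier batch is argued against as its cause, because the later batch alone gave a difference of 0.284 (exact permutation p = 0.012). Wrong calls scattered over single bins in either stage are argued against, because they would add changes and lower agreement together. The 8-cell stage instead had 22.8 more changes per 1000 bins and the higher agreement. Wrong calls that span many neighbouring bins need not add changes, so this argument does not cover them. The authors' noise score differed by -0.015 between the stages (exact permutation p = 0.657), which excludes no difference in noise, whether the score measures it or not. In the later batch it was 0.646 ± 0.115 (SD, n = 4 embryos) at the 4-cell and 0.608 ± 0.056 (SD, n = 10) at the 8-cell stage (exact permutation p = 0.433). The 2 mid-S cells of 4-cell embryo 6 had the highest scores of all cells, 0.801 and 0.805. A difference between batches within the 4-cell stage and an effect of the stage itself cannot be told apart: the later 4-cell batch was lower in agreement than the earlier by -0.25 (exact permutation p = 0.0794, 4 against 5 embryos; -0.151 with block bins left out, p = 0.135) and changed state less by -24.2 (p = 0.0238; -18.9 with block bins left out, p = 0.0238), and the 8-cell embryos exceeded the earlier 4-cell batch by 0.0347 (exact permutation p = 0.35).

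The 18 windows that differed between the stages were set against other groupings of the same embryos. Of 100 splits, the real one included, 1 called as many, and the highest of the others called 1 window. So many calls were thus rare among splits drawn without regard to batch. Only 100 of 92378 possible splits were tried, so chance is made unlikely but is not excluded. The splits did not hold the batches fixed, and 5 of the 9 4-cell embryos come from the earlier batch, which has no 8-cell embryo, so a batch difference is not excluded by them. The real split also gave 398 windows at an unadjusted p under 0.05 in limma, and the highest of the others gave 273.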
